A study of Mus musculus with 12 samples.

How the data were processed

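Lacrimal gland RNA was sequenced from 4 groups of mice with 3 libraries each: control, ESS, and NOD at 8 and 12 weeks. Per the labels, RNA was extracted with Trizol, 1-2 ug of total RNA went into each library, libraries were made with a stranded KAPA kit, and the genome build was GRCm38. The authors gave expression as FPKM (fragments per kilobase of transcript, scaled to library size), per the file headers, in a table of 11736 genes and a table of 21202 transcripts. The aligner and the annotation release are not given in the sources used here. Every gene listed is of the protein-coding type and has a mean of at least 0.5 FPKM in at least 1 group, which is read from the values, and 10 symbols belong to 2 genes each. Of the gene identifiers, 10224 were found with their version in GENCODE M21, all with identical coordinates, and 11715 were found ignoring the version. In 1302 of 1302 genes that could be checked, the gene value equalled, within 1%, the sum of transcript FPKM times length over the joined exon length. No file gives counts, so count models were not used here.

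The depth behind the values is known in relative terms alone. The lowest values fall on regular steps, with 42.9% to 52.9% of them within 0.1 of a whole multiple where chance gives 20%, and the size of the steps puts the libraries at 0.781 to 1.12 times their mean depth. Whole read numbers were not recovered, so no counting interval is given. Values are mean ± SD of 3 libraries.

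Values were analysed as log2(FPKM + 1), and fold changes on this scale understate those of genes with low values. Genes with at least 1 FPKM in at least 3 of the 12 libraries were tested, 10325 in all. A linear model with a mean for each of the 4 groups was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3, using moderated statistics with a trend, and the Benjamini-Hochberg adjusted p was held to 0.05. The 6 comparisons were each of the other groups against control, 12 against 8 weeks in NOD, and ESS against each NOD age. All libraries were placed in a group by their titles, and none was left out.

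Before the data were examined, 36 gene lists of cell types, pathways and neighbouring tissues were fixed. The 28 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. With the estimated correlation 0 lists passed in any of the 6 comparisons. The rotation test fry, which asks whether the members of a list move on balance to one side, passed 1, 15, 13, 0, 8 and 6 lists in the order of the comparisons above. Its variance step depends on the order of the libraries, and over 20 random orders it passed 12 to 13 lists in NOD at 12 weeks against control and 6 to 8 in ESS against either NOD age, with the other 3 counts unchanged. Calls of members were counted over all genes and adjusted over the list alone. The 5 sex check genes had no values in the table, which lists only protein-coding genes with a mean of at least 0.5 FPKM in a group. Low values and omission by the authors cannot be told apart there, so the sex of the mice was not read from it. The rule for named genes, also fixed beforehand, took the 8 largest rises and 8 largest falls against control (5 and 5 in the other comparisons) among called genes with a mean of at least 5 FPKM in the higher group and no overlap between groups, and of each list the 4 members (or 2) with the smallest adjusted p. It left out predicted genes and immunoglobulin and T cell receptor segments. Some results on single genes chosen by this rule are not reported here.

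Shared calls were set against independent calls and against 100 simulated unchanged groups compared with the same control libraries. Alternatives tried were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, quantile normalization, centred library medians, a robust prior, the compared groups alone, a replicate block, a fold change of at least 2, transcript values summed per gene, and leaving out each library in turn. Rescaling without the 46 most abundant genes, and leaving out both ESS libraries with salivary transcripts, were chosen after seeing the data. Each set of 6 libraries was also split into 3 and 3 in the 10 possible ways. The procedure was tested on simulated data of 10325 genes, with independent noise per gene and the same spread in all groups. For ESS against control it recovered 85 of 100 genes changed 2-fold and 98 of 100 changed 4-fold, and it called 9 unchanged genes. Real genes may vary together and groups may differ in spread, so these shares do not measure the power in the real data.

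Exact tests were made with scipy 1.17.1 and Python 3.11.15, tables with pandas 2.3.3, sequence comparison with blastn 2.17.0 against GENCODE M21 transcripts (a copy being at least 95% identical over at least 50% of the longest transcript), and figures with matplotlib 3.10.9.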

Results

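RNA sequencing compared the lacrimal gland, which makes the watery part of tears, in 4 groups of mice with 3 libraries each. The groups were control mice, mice labelled ESS, and NOD mice aged 8 weeks and 12 weeks. NOD (non-obese diabetic) mice are an inbred strain prone to autoimmune disease, including inflammation of the tear and salivary glands. The study's description speaks of LGSS mice where the sample labels have ESS, and both were taken as the same group because the other groups are accounted for. Sjögren's syndrome is an autoimmune disease of those glands, and the comparisons ask how a model of it raised with a lacrimal autoantigen differs from control and from NOD glands. The sex of the mice, and the strain and ages of the control and ESS mice, are not given in the sources used here. Strain, sex and age therefore cannot be separated from any difference between control, ESS and NOD glands. The labels do not say whether each library came from a separate animal, so the p-values measure only the spread between samples.

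Expression was given as FPKM for 11736 protein-coding genes, of which 10325 reached the level for testing. The number of reads behind each library is not given in the sources used here. The spacing of the lowest values put the depth of the libraries at 0.781 to 1.12 times their mean, while the absolute depth stayed unknown. The 20 most abundant genes held 62.6% to 76.3% of the listed FPKM. Secretoglobins, small secreted proteins, held 22.3% to 31.3% of it in control and ESS glands and 38.9% to 44.2% in NOD glands. ESS libraries 1 and 2 stood apart in another way, by abundant transcripts of salivary gland genes that ESS library 3 had at low levels. Component 1 of a principal component analysis held 51.3% of the variance and separated NOD from the other glands, and component 2 held 10.9%.

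**Figure D1:**
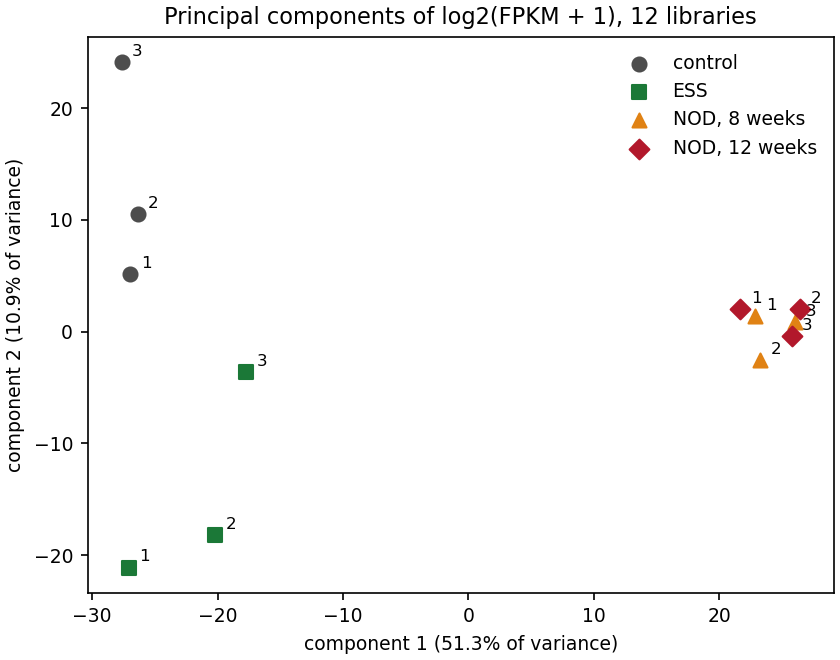
Principal components of log2(FPKM + 1) in the 12 libraries, with component 1 (51.3% of the variance) on the x axis and component 2 (10.9%) on the y axis. Each point is a library, its number is the replicate, and the NOD libraries of both ages lie together on the right, away from control and ESS.

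In ESS against control glands, the transcript of Jchain, the joining chain of secreted IgA and IgM made by plasma cells, rose from 2.18 ± 0.514 to 14.3 ± 1.80 FPKM (SD, n = 3). Its log2 fold change was 2.27 (SE 0.17, adjusted p = 0.000187), all 3 ESS libraries lay above all 3 control libraries, and the call held under every alternative tried. Jchain (ENSMUSG00000067149.6) lies on chromosome 5 of GRCm38 at 88519809 to 88527891. Dio1, a deiodinase that activates thyroid hormone, fell from 17.5 ± 13.6 to 0.763 ± 0.455 FPKM (log2 fold change -3.07, SE 0.48, adjusted p = 0.0382). Sox9, a transcription factor of duct and progenitor epithelium, fell from 50.1 ± 3.96 to 35.7 ± 0.726 FPKM (log2 fold change -0.47, adjusted p = 0.0413). Mt1, a metal-binding metallothionein, fell by 0.90 on the log2 scale (adjusted p = 0.0439).

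Of the 10325 genes, 7 rose and 10 fell in ESS glands, and 1245 had an unadjusted p under 0.05. The other rises were Scgb1b27, a secretoglobin (log2 fold change 3.42), Cbs, an enzyme of cysteine synthesis (1.70), Asgr1, a hepatic-type lectin receptor (1.19), Sardh (0.90), Rab39b (0.82) and Hcar2 (0.75). Scgb1b27 reached 120 and 50.5 FPKM in the ESS libraries with salivary transcripts and 22.2 FPKM in ESS library 3, against 3.96 ± 0.804 FPKM in control (n = 3). The other falls were Ctdsp2 (-2.14), Cdc42se1 (-1.56), Aldh1a7 (-1.21), Tacc3 (-0.78), Pola2 (-0.74), Slc39a8 (-0.69) and Ucn2 (-0.64). Rab39b, Aldh1a7, Tacc3 and Pola2 fall outside the rule for named genes and were chosen after their values were seen.

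Plasma cell markers moved up as a list in ESS glands, with 1 of 4 tested members risen, 0 fallen and 3 not passing, or 2 risen when adjusted over the list alone. The list gave camera adjusted p = 0.00721, and adjusted p = 0.355 with an estimated correlation. Its member Mzb1, a chaperone of antibody assembly, had 0.727 ± 0.471 against 0.150 ± 0.164 FPKM (adjusted p = 0.255). The remaining tested members, Derl3 and Sdc1, showed no rise. Derl3 had a log2 fold change of -0.042, and Sdc1 had 5.28, 5.97 and 5.87 FPKM in ESS against 7.34, 5.76 and 6.76 FPKM in control. The movement of the list thus rests on Jchain and Mzb1. Of the list's 12 members, the immunoglobulin genes are outside the protein-coding gene type and were not analysed here. Proliferation genes moved down as a list, with 0 of 6 members called over all genes and all 6 fallen when adjusted over the list alone (camera adjusted p = 1.24e-06, and adjusted p = 0.355 with an estimated correlation). Mki67, a marker of dividing cells, had 0.762 ± 0.0916 FPKM against 2.83 ± 1.31 FPKM in control, where control library 2 had 1.36 FPKM.

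Type I interferon response genes moved down as a list, with 0 of 15 members called over all genes and 0 when adjusted over the list alone. Their median log2 fold change was -0.51 (camera adjusted p = 0.000984, and adjusted p = 0.711 with an estimated correlation). Usp18, an interferon-induced regulator, had 2.36 ± 1.56 against 7.00 ± 2.98 FPKM (adjusted p = 0.168). Genes of the unfolded protein response, which handles misfolded secretory proteins, moved up as a list with 0 of 14 members called and 1 risen when adjusted over the list alone (camera adjusted p = 0.00721, and adjusted p = 0.711 with an estimated correlation). Its member Calr, a chaperone of the endoplasmic reticulum, had 442 ± 2.98 against 317 ± 46.1 FPKM (adjusted p = 0.141). Complement genes moved up as a list, with 0 of 9 members called and 0 when adjusted over the list alone (camera adjusted p = 0.0380, and adjusted p = 0.711 with an estimated correlation). C3, the central complement protein, had a log2 fold change of 0.44.

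Salivary gland markers moved up as a list, with 0 of 4 tested members called over all genes and 3 risen when adjusted over the list alone. The list gave camera adjusted p = 5.1e-05, and adjusted p = 0.355 with an estimated correlation. Bpifa2, a secreted protein of the parotid gland, had 3906 ± 3536 against 4.74 ± 7.05 FPKM (adjusted p = 0.110). It reached 6915 and 4790 FPKM in ESS libraries 1 and 2 and 12.2 FPKM in ESS library 3. Smr3a and the salivary amylase Amy1 had log2 fold changes of 7.53 and 6.32.

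**Figure D2:**
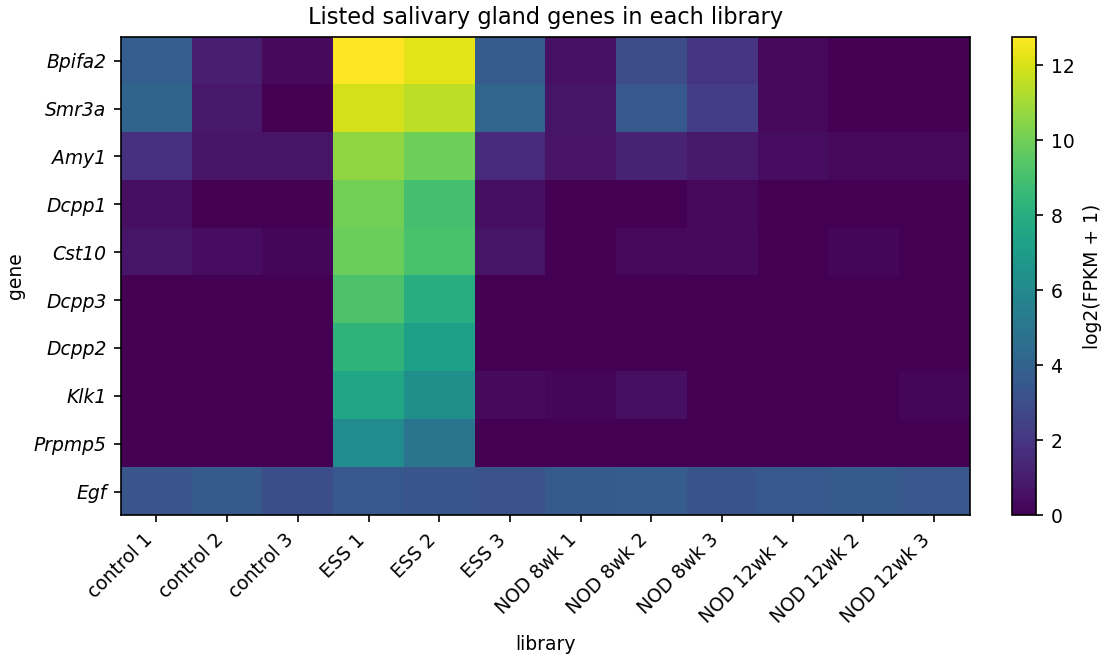
Listed salivary gland genes (y axis) in each of the 12 libraries (x axis), coloured by log2(FPKM + 1). In 9 of the 10 genes, ESS libraries 1 and 2 stand above the other 10 libraries, while Egf is alike in all.

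Of 15 T cell markers 4 had values and 1 was tested, and of 13 B cell markers 1 had values and 0 were tested. The tested one, Thy1, had 4.47 ± 0.746 FPKM in ESS and 5.57 ± 1.23 FPKM in control glands (adjusted p = 0.650). Antigen presentation lists of both classes did not pass in ESS against control. H2-T23, a class I molecule, had 40.6 ± 4.38 against 47.9 ± 0.832 FPKM (adjusted p = 0.586). Cd74, the class II invariant chain, had 167 ± 51.6 against 213 ± 49.3 FPKM (adjusted p = 0.547).

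The count of 17 genes was small and moved with single libraries, to 8 without ESS library 1, 1 without ESS library 2, 75 without control library 2 and 3 without control library 3, and it was 21, of which 3 were among the 17, without both ESS libraries with salivary transcripts, a comparison of 1 ESS library that is assumed to vary like the other groups. Among the 17 genes the share of rises was 41.2%, with 17 rises and 10 falls after quantile normalization, 15 and 5 with centred library medians and 13 and 50 after rescaling without the most abundant genes, and groups of 3 that did not overlap made up 18.2% of tested genes where chance gives 10%. The call of plasma cell markers ended with a filter at 5 FPKM (adjusted p = 0.0899), and that of type I interferon response with that filter or without ESS library 2 (highest adjusted p 0.347). The call of the unfolded protein response ended after quantile normalization and without ESS library 2 or control library 1 (highest adjusted p 0.154). The call of complement ended with the 5 FPKM filter, with centred library medians, with transcript values summed, without ESS library 1 or control library 3, and with the lone ESS library 3 (highest adjusted p 0.949).

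In NOD glands at 8 weeks against control, Jchain and Mzb1 rose while Ly6e and transcripts of histocompatibility genes fell. Jchain was 31.8 ± 6.89 FPKM against 2.18 ± 0.514 FPKM in control (n = 3), and Mzb1 rose from 0.150 ± 0.164 to 1.95 ± 0.210 FPKM (adjusted p = 0.000296). Ly6e, an interferon-inducible surface protein, fell from 373 ± 35.3 to 1.98 ± 1.28 FPKM (adjusted p = 2.25e-08). H2-K1, a classical class I histocompatibility molecule, fell from 71.6 ± 7.16 to 5.66 ± 1.50 FPKM (adjusted p = 1.4e-07), and H2-Aa, a class II chain, fell from 78.0 ± 13.2 to 14.0 ± 1.68 FPKM (adjusted p = 3.94e-06). Mucl1, a mucin-like secreted protein, was 90.2 ± 11.1 FPKM against 0.0970 ± 0.0859 FPKM (adjusted p = 6.68e-10), and Scgb2b3, a secretoglobin, was 2882 ± 744 against 7.62 ± 4.97 FPKM (adjusted p = 1.48e-07).

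A total of 547 genes rose and 2278 fell, or 19.4% higher, and the median log2 fold change of all genes was -0.15. Quantile normalization shifted that median by 0.16 and gave 1134 rises and 1265 falls, centring the library medians shifted it by 0.17 and gave 1266 and 1150, and rescaling without the most abundant genes shifted it by 0.12 and gave 919 and 1374. The log2 changes of this comparison are therefore given relative to the median of all genes. Calls of genes and their adjusted p-values, here and below, test the changes before that median is taken off. Other large rises were Esp24, an exocrine gland peptide (7.43), Scgb1b3 (6.42), Mup5, a major urinary protein (6.36), and Dgat2, an enzyme of triglyceride synthesis (3.97). Further large falls were Dio1 (-3.64), the small GTPase Rasd2 (-3.13), the ribosomal protein gene Rpl29 (-3.23), the protease inhibitor Wfdc12 (-3.11) and the class I molecule H2-T23 (-3.17). All of these kept their calls under every alternative tried.

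Plasma cell markers rose in 3 of 4 tested members, with 0 fallen and 1 not passing, and equally when adjusted over the list alone, with a median of 1.03 relative to all genes (camera adjusted p = 0.00015, and adjusted p = 0.162 with an estimated correlation). Beside Jchain and Mzb1 the third was Derl3, with 60.8, 63.8 and 58.5 FPKM against 43.3, 46.0 and 48.4 FPKM in control. Jchain had 2.73, 2.09 and 1.71 FPKM in those control libraries. Whether the rise of Derl3 comes from plasma cells was not tested. Class I antigen presentation genes fell in 11 of 11 tested members, also when adjusted over the list alone (median -0.66, camera adjusted p = 5.25e-06, and adjusted p = 0.407 with an estimated correlation). Among them B2m, the light chain of class I molecules, fell from 210 ± 42.8 to 58.9 ± 0.892 FPKM (adjusted p = 0.00016). Class II genes fell in 6 of 7 tested members, also when adjusted over the list alone, and 1 did not pass (median -1.65, camera adjusted p = 7.74e-05, and adjusted p = 0.407 with an estimated correlation). Of both lists, 13 genes lie in the histocompatibility region of chromosome 17 and 4 on other chromosomes. For the 13, a mismatch of a NOD haplotype to the reference genome stays open, so their lower values may not be lower expression.

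Type I interferon response genes fell in 13 of 15 tested members, and in all 15 when adjusted over the list alone (median -1.16, camera adjusted p = 2.71e-05, and adjusted p = 0.538 with an estimated correlation). Bst2, which tethers budding viruses, fell by 1.68 relative to all genes (adjusted p = 1.32e-05), and Oas1a, a sensor of double-stranded RNA, fell by 1.78 (adjusted p = 0.000556). Interferon gamma response genes fell in 9 of 11 members, and in all 11 when adjusted over the list alone (median -0.87, camera adjusted p = 0.00155, and adjusted p = 0.558 with an estimated correlation). Proliferation genes fell in 6 of 6 members, also when adjusted over the list alone (median -1.18, camera adjusted p = 0.000773, and adjusted p = 0.508 with an estimated correlation). Mki67 was 0.409 ± 0.177 FPKM against 2.83 ± 1.31 FPKM in control.

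Unfolded protein response genes rose in 7 of 14 members, with 0 fallen and 7 not passing, and also 7 when adjusted over the list alone (median 0.56, camera adjusted p = 1.71e-05, and adjusted p = 0.407 with an estimated correlation). Calr rose from 317 ± 46.1 to 516 ± 45.3 FPKM (adjusted p = 0.00171), and Hspa5, the main chaperone of the endoplasmic reticulum, from 183 ± 10.4 to 258 ± 9.91 FPKM (adjusted p = 0.0138). Immediate early genes, which respond within minutes to stimulation or handling, moved up as a list with 0 of 10 members called and 0 when adjusted over the list alone (median 1.13, camera adjusted p = 0.00105, and adjusted p = 0.558 with an estimated correlation). Egr1 among them had 19.0 ± 12.6 against 6.46 ± 6.19 FPKM (adjusted p = 0.158). Macrophage and monocyte markers fell in 8 of 14 members while the list did not pass (camera adjusted p = 0.0507), and C1qa, a complement protein made by macrophages, fell from 53.2 ± 8.22 to 21.3 ± 1.52 FPKM (adjusted p = 0.000477).

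Among genes of lacrimal secretion, Pigr, the receptor that carries IgA across epithelium, fell from 221 ± 48.1 to 89.9 ± 11.3 FPKM (adjusted p = 0.000116). Kcnn4, a calcium-activated potassium channel, fell from 5.93 ± 1.29 to 2.58 ± 0.134 FPKM (adjusted p = 0.00629), and Itpr3, a calcium release channel, rose from 6.58 ± 0.517 to 10.1 ± 1.62 FPKM (adjusted p = 0.00639). Lcn11 of the same list had 5976, 6821 and 6360 FPKM at 8 weeks against 3692, 2185 and 3121 FPKM in control. The list itself did not pass. Thy1 fell from 5.57 ± 1.23 to 2.71 ± 0.843 FPKM (adjusted p = 0.0127), a call that ended without NOD library 3 and with a fold change of at least 2. The lymphoid chemokine Cxcl13 had 1.87 ± 1.19 against 0.381 ± 0.431 FPKM (adjusted p = 0.0451). Its call ended without NOD library 1 or 2 or control library 2 or 3, and with a fold change of at least 2 on the log2(FPKM + 1) scale. With a filter at 5 FPKM it was not tested. The call of interferon gamma response ended with a filter at 5 FPKM (adjusted p = 0.172). The call of immediate early genes ended after quantile normalization, with centred medians, without NOD library 3 and without control library 2 (highest adjusted p over its alternatives 0.109).

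**Figure D3:**
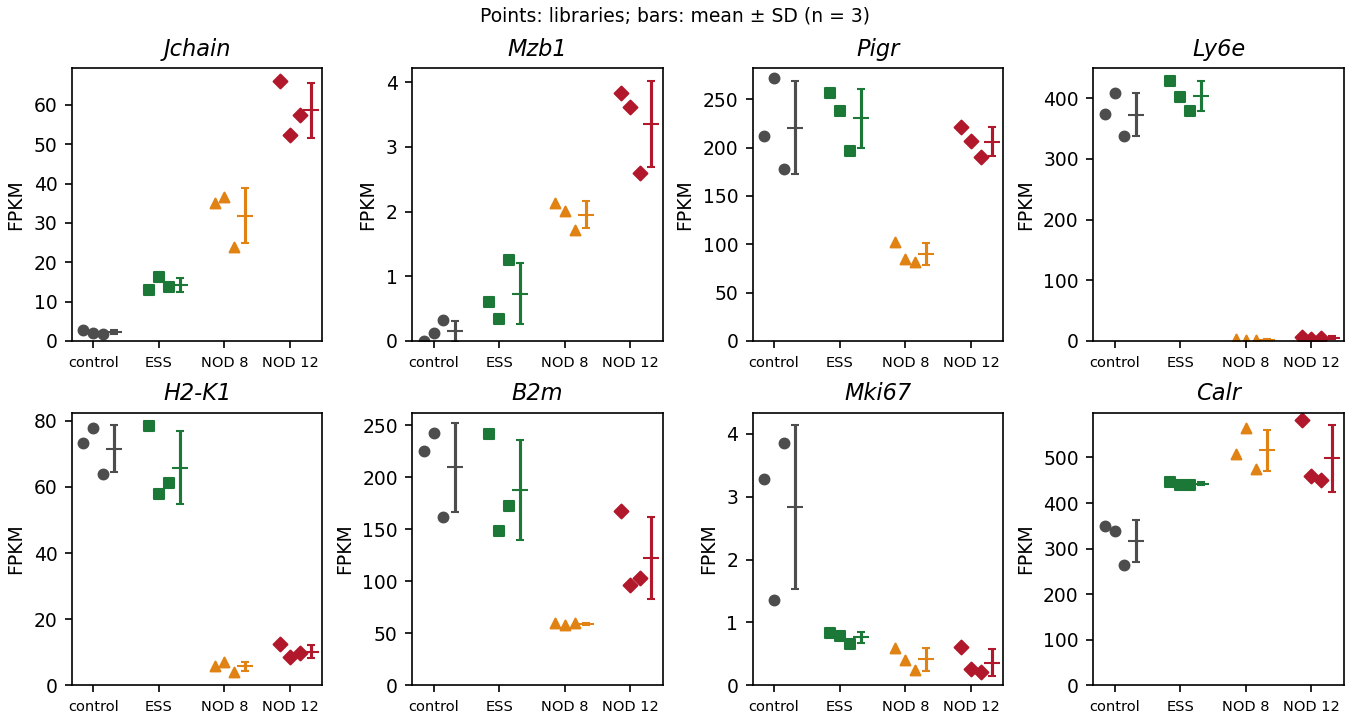
FPKM (y axis) of 8 genes in the 12 libraries by group (x axis, NOD 8 and NOD 12 being the ages in weeks). Points are libraries and bars the mean ± SD of 3, and Jchain lies above control in all 3 ESS and all 6 NOD libraries.

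In NOD glands at 12 weeks against control, Jchain and Mzb1 again rose, and Ly6e, H2-K1 and H2-Aa again fell. Jchain was 58.6 ± 7.01 FPKM against 2.18 ± 0.514 FPKM (n = 3, adjusted p = 2.04e-08), and Mzb1 was 3.35 ± 0.665 FPKM against 0.150 ± 0.164 FPKM (adjusted p = 2.09e-05). Ly6e fell to 5.07 ± 2.25 FPKM (adjusted p = 6.68e-08), H2-K1 to 10.1 ± 2.00 FPKM (adjusted p = 1.01e-06) and H2-Aa to 18.0 ± 5.50 FPKM (adjusted p = 1.16e-05). Mucl1 was 68.7 ± 15.3 FPKM and Scgb2b3 was 1717 ± 297 FPKM, against 0.0970 ± 0.0859 and 7.62 ± 4.97 FPKM in control. Pigr was 206 ± 15.2 FPKM, against 221 ± 48.1 FPKM in control.

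At this age 570 genes rose and 2874 fell, or 16.6% higher, with a median of all genes of -0.18. Each of the 3 scalings, quantile normalization, centring and rescaling, shifted that median by 0.18 to 0.19, and they gave 1300 rises and 1347 falls, 1308 and 1241, and 1198 and 1243. Other large changes, relative to the median of all genes, included rises of Esp24 (7.33), Scgb1b3 (5.86), Dgat2 (4.02) and Mup5 (3.99) and falls of the class I molecule H2-T22 (-3.76), Dio1 (-3.61), H2-T23 (-3.32), Rasd2 (-3.10) and Rpl29 (-3.09). These kept their calls under every alternative tried.

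Plasma cell markers rose in 2 of 4 members, Jchain and Mzb1, and in 3 when adjusted over the list alone (median 1.30 relative to all genes, camera adjusted p = 0.000495, and adjusted p = 0.175 with an estimated correlation). Class II genes fell in 6 of 7 members, also when adjusted over the list alone (median -1.27, camera adjusted p = 0.00159, and adjusted p = 0.763 with an estimated correlation), and class I genes in 7 of 11, or 10 when adjusted over the list alone (median -0.38, camera adjusted p = 0.00176, and adjusted p = 0.763 with an estimated correlation). For those in the histocompatibility region, a mismatch of a NOD haplotype to the reference genome stays open here too. Proliferation genes fell in 6 of 6 members, also when adjusted over the list alone (median -1.19, camera adjusted p = 0.00206, and adjusted p = 0.763 with an estimated correlation). Unfolded protein response genes rose in 7 of 14, or 8 when adjusted over the list alone (median 0.58, camera adjusted p = 2.45e-06, and adjusted p = 0.426 with an estimated correlation), with Calr at 498 ± 73.8 FPKM against 317 ± 46.1 FPKM (adjusted p = 0.00251).

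Type I interferon response genes fell in 11 of 15 members, or 13 when adjusted over the list alone (median -0.71, camera adjusted p = 0.0145, and adjusted p = 0.817 with an estimated correlation). Interferon gamma response genes fell in 8 of 11, or 9 when adjusted over the list alone (median -0.66, camera adjusted p = 0.0336, and adjusted p = 0.794 with an estimated correlation). Genes of cholesterol synthesis and transport moved up as a list, with 1 of 15 members risen and 1 fallen, or 1 risen when adjusted over the list alone (median 0.29, camera adjusted p = 0.0155, and adjusted p = 0.763 with an estimated correlation). Sqle, an enzyme of cholesterol synthesis, had 0.998, 0.692 and 0.610 FPKM against 1.17, 1.50 and 1.34 FPKM in control and was called as fallen. That call ended without NOD library 2 or 3 or control library 2 or 3, and with a fold change of at least 2. It was made before the median of all genes, -0.18 on the log2 scale, is taken off. Immediate early genes moved up as a list with 0 of 10 members called and 0 when adjusted over the list alone (median 1.12, camera adjusted p = 0.00161, and adjusted p = 0.763 with an estimated correlation). Of the list calls, both interferon lists ended with a filter at 5 FPKM and without NOD library 1 or control library 2 (highest adjusted p 0.238 and 0.335), cholesterol with that filter and without NOD library 1 (0.208), and immediate early genes without control library 2 and under each of the 3 scalings (0.0904).

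**Figure D4:**
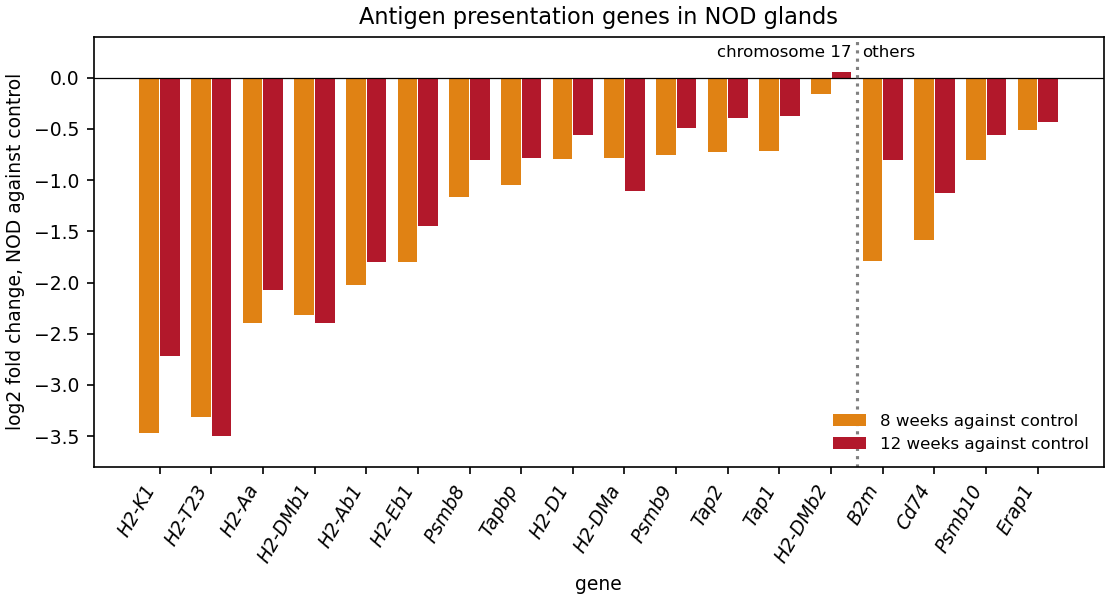
Log2 fold changes (y axis) of antigen presentation genes (x axis) in NOD against control glands at 8 and 12 weeks (n = 3 per group), with genes of chromosome 17 left of the dotted line. The medians of all genes were -0.15 and -0.18, and H2-K1 and H2-T23 lie lowest.

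Between the ages, 8 genes rose and 5 fell from 8 to 12 weeks in NOD glands. Pigr rose from 89.9 ± 11.3 to 206 ± 15.2 FPKM (log2 fold change 1.19, SE 0.15, adjusted p = 0.0110, n = 3). Igfbp3, which binds insulin-like growth factors, fell from 11.7 ± 1.22 to 4.19 ± 0.384 FPKM (-1.29, adjusted p = 0.00398). Hspa8, a constitutive heat shock chaperone, fell by 1.18 and Tsc22d3, a glucocorticoid-induced regulator, fell by 0.88 on the log2 scale. Ifi27, an interferon-inducible gene, rose from 61.8 ± 6.79 to 117 ± 2.61 FPKM (0.92, adjusted p = 0.0135).

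The other rises were Asgr1 (1.15), Npas2, a clock transcription factor (1.11), Myoc (0.99), Calml4 (0.97), Olfm4 (0.84) and Slc25a35 (0.69), and the other falls were the secretoglobin Scgb1b10 (-2.18) and Coa6 (-0.82). Npas2, Myoc and Olfm4 fall outside the rule for named genes and were chosen after their values were seen. Class I presentation genes moved up as a list with 0 of 11 members called and 2 risen when adjusted over the list alone (median log2 fold change 0.27, camera adjusted p = 9.61e-06, and adjusted p = 0.716 with an estimated correlation). Type I interferon response genes did so with 0 of 15 called and 1 when adjusted over the list alone (0.41, camera adjusted p = 9.61e-06, and adjusted p = 0.716 with an estimated correlation). Cholesterol genes moved up with 0 of 15 called and 2 when adjusted over the list alone (0.20, camera adjusted p = 0.00161, and adjusted p = 0.716 with an estimated correlation).

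Extracellular matrix genes moved down as a list from 8 to 12 weeks, with 0 of 12 members called and 3 fallen when adjusted over the list alone (median -0.53, camera adjusted p = 0.00161, and adjusted p = 0.716 with an estimated correlation). Basal and myoepithelial genes moved down with 0 of 9 called and 0 when adjusted over the list alone (-0.21, camera adjusted p = 0.0271, and adjusted p = 0.716 with an estimated correlation). Col1a1, a fibrillar collagen chain, had a log2 fold change of -0.74, and Acta2, the smooth muscle actin, one of -0.38, and neither passed. Jchain had a log2 fold change of 0.88 and did not pass. The 13 genes became 6 without NOD library 2 and 7 without library 3 of 12 weeks, and 20 rose and 6 fell after rescaling without the most abundant genes, with 934 genes at an unadjusted p under 0.05 and non-overlapping groups in 15.5% of tested genes where chance gives 10%. Pigr lost its call without library 2 of either age, while Igfbp3 kept it under every alternative tried, and the basal and myoepithelial call ended after quantile normalization and without NOD library 1 of 12 weeks or 1 or 3 of 8 weeks (highest adjusted p 0.246), and the cholesterol call ended with a filter at 5 FPKM (0.0973).

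**Figure D5:**
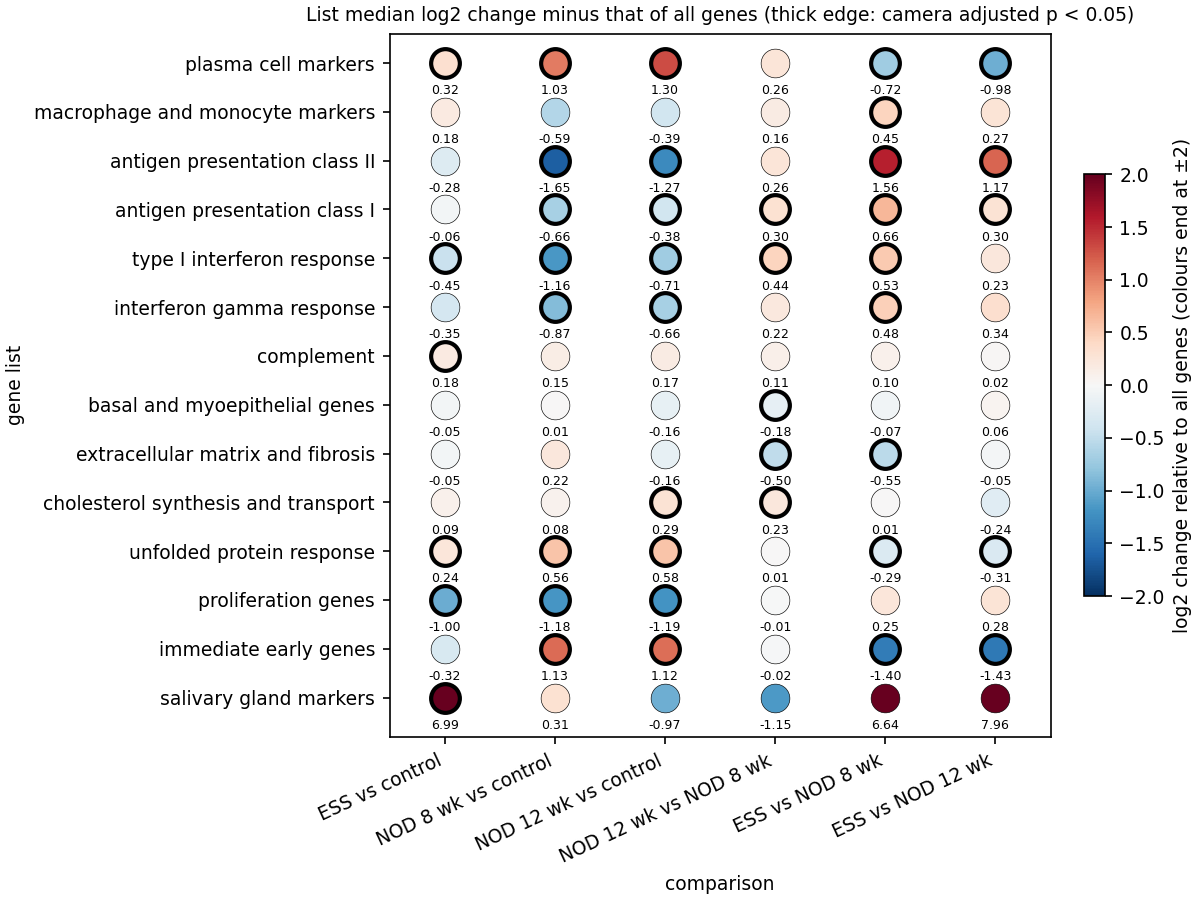
Median log2 change of each gene list (y axis) minus that of all genes, in each comparison (x axis), for lists that passed camera in at least 1 comparison. Thick edges mark camera adjusted p under 0.05, colours end at 2 and -2, and plasma cell markers lie above 0 in all 3 comparisons with control and below 0 in ESS against NOD.

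In ESS against NOD glands, Jchain was lower and Ly6e and H2-K1 were higher. Jchain was 14.3 ± 1.80 FPKM in ESS against 31.8 ± 6.89 FPKM at 8 weeks (adjusted p = 0.00108) and 58.6 ± 7.01 FPKM at 12 weeks (adjusted p = 1.08e-05, n = 3). Ly6e was 403 ± 24.3 FPKM in ESS against 1.98 ± 1.28 and 5.07 ± 2.25 FPKM (adjusted p = 2.1e-08 and 6.7e-08), and H2-K1 was 65.8 ± 11.0 FPKM against 5.66 ± 1.50 and 10.1 ± 2.00 FPKM. Kcnn4 was 12.1 ± 3.92 FPKM in ESS against 2.58 ± 0.134 and 2.90 ± 0.649 FPKM (adjusted p = 0.000101 and 0.000159). The secreted proteins Mucl1, Scgb2b3, Scgb1b3 and Esp24 were lower in ESS than in NOD glands at both ages, with log2 changes of -6.38, -8.36, -5.81 and -5.76 relative to all genes at 8 weeks. Mt2, a metallothionein, was 4.43 ± 1.48 FPKM in ESS against 71.2 ± 3.44 FPKM at 12 weeks (adjusted p = 1.11e-06).

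Against 8 weeks, 1163 genes were higher and 407 lower in ESS, or 74.1% higher, with a median of all genes of 0.09. Quantile normalization, centring and rescaling shifted that median by -0.10, -0.10 and -0.16, and gave 821 higher and 759 lower, 794 and 766, and 606 and 979. Against 12 weeks, 1670 were higher and 458 lower, or 78.5% higher, with a median of 0.12. The same scalings shifted it by -0.13, -0.12 and -0.23, and gave 905 and 900, 931 and 831, and 556 and 1439. Without both ESS libraries with salivary transcripts, which leaves 1 ESS library that is assumed to vary like the other groups, the counts were 552 and 586, of which 514 and 547 were among those with all libraries. The count against 12 weeks was 1261 without NOD library 2 and 1327 without NOD library 3.

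Here the list medians are relative to all genes, while the member counts are calls before the median of all genes is taken off. Class II genes were higher in ESS in 5 of 7 members at 8 weeks, also when adjusted over the list alone (median 1.56, camera adjusted p = 0.000156, and adjusted p = 0.543 with an estimated correlation). They were higher in 6 of 7 at 12 weeks, also when adjusted over the list alone (1.17, camera adjusted p = 0.00129, and adjusted p = 0.899 with an estimated correlation). Class I genes were higher in 10 of 11, or 11 when adjusted over the list alone (0.66, camera adjusted p = 2.78e-07, and adjusted p = 0.43 with an estimated correlation), and in 5 of 11, or 8 (0.30, camera adjusted p = 0.00129, and adjusted p = 0.899 with an estimated correlation). In both classes, a mismatch of a NOD haplotype to the reference genome stays open for genes of the histocompatibility region. Plasma cell markers were lower in 3 of 4, also when adjusted over the list alone (-0.72, camera adjusted p = 0.00107, and adjusted p = 0.276 with an estimated correlation), and in 2 of 4, or 3 (-0.98, camera adjusted p = 0.000749, and adjusted p = 0.198 with an estimated correlation). Unfolded protein response genes were lower in 1 of 14 (-0.29, camera adjusted p = 0.00228, and adjusted p = 0.64 with an estimated correlation) and in 3 of 14 (-0.31, camera adjusted p = 0.000949, and adjusted p = 0.899 with an estimated correlation), with the same counts when adjusted over the list alone. Trib3, a stress-induced pseudokinase of that list, was 0.987 ± 0.134 FPKM in ESS against 3.62 ± 0.310 FPKM at 8 weeks (adjusted p = 0.00142).

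Immediate early genes were lower in ESS, with 1 of 10 members passing at 8 weeks, or 2 when adjusted over the list alone (-1.40, camera adjusted p = 0.000355, and adjusted p = 0.64 with an estimated correlation), and 0 of 10 at 12 weeks, also when adjusted over the list alone (-1.43, camera adjusted p = 0.000686, and adjusted p = 0.952 with an estimated correlation). Against 8 weeks, macrophage markers were higher in 6 of 14 members, or 7 when adjusted over the list alone (0.45, camera adjusted p = 0.00693, and adjusted p = 0.64 with an estimated correlation), with C1qa at 50.8 ± 11.4 against 21.3 ± 1.52 FPKM. Type I interferon genes were higher in 3 of 15, or 5 when adjusted over the list alone (0.53, camera adjusted p = 0.00237, and adjusted p = 0.64 with an estimated correlation), and interferon gamma genes in 2 of 11, or 3 (0.48, camera adjusted p = 0.0194, and adjusted p = 0.64 with an estimated correlation). Extracellular matrix genes moved down as a list although 1 of 12 members was higher, Tgfb1, a growth factor, also when adjusted over the list alone (-0.55, camera adjusted p = 0.0162, and adjusted p = 0.64 with an estimated correlation). Bpifa2, Smr3a, Amy1 and the chitinase Chia1 passed as higher in ESS, with 2 ESS libraries holding the salivary transcripts. Without NOD library 3 of 8 weeks, the calls of the unfolded protein response and of immediate early genes ended (highest adjusted p 0.0644 and 0.0751), that of interferon gamma ended with a filter at 5 FPKM and without ESS library 1 or 3 or NOD library 2 (0.325), and that of matrix genes ended under each scaling and with the lone ESS library 3 (0.102). Against 12 weeks, the call of immediate early genes ended after rescaling without the most abundant genes (0.0712).

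Changes against control were shared between the models in part. Of the 17 genes called in ESS, 15 passed in the same direction in NOD glands at 8 weeks, 6 of them higher and 9 lower, where independent calls would give 0.371 and 2.21. At 12 weeks 13 did so, 6 higher and 7 lower, against 0.386 and 2.78. Jchain, Asgr1, Sardh, Rab39b and Hcar2 rose, and Dio1, Sox9, Tacc3, Pola2, Ucn2, Slc39a8 and Aldh1a7 fell, in all 3 comparisons with control, while Mt1 fell in ESS and rose in NOD glands of both ages. The size of the Jchain rise differed, by -1.09 between ESS and 8 weeks and by -1.96 between ESS and 12 weeks on the log2 scale. Both NOD ages shared 2308 calls of the same direction, 412 higher and 1896 lower, where independent calls would give 30.2 and 634.

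All these comparisons use the same 3 control libraries. Simulated unchanged groups set against them make almost no calls, so their shared calls (a mean of 0.01 and 0.02, 1 at most) do not measure what shared controls add to an overlap with the many calls of NOD glands. The correlation of ESS and NOD fold changes across genes, which are not independent replicates, was 0.386 at 8 weeks and 0.371 at 12 weeks, below the 0.50 and 0.50 that shared controls alone gave, while the covariance was 0.0575 and 0.0546 against 0.0193 and 0.0194. Between both NOD ages the correlation was 0.904 against 0.50 from shared controls alone, and the covariance 0.232 against 0.0195. The simulation gave all groups the same spread, which fixes its correlation near 0.50. Real libraries correlated less within control (median 0.972) than within ESS (0.978) or either NOD age (0.984). Shared controls may therefore add more covariance than was simulated, and how much more was not tested. The overlap at 8 and 12 weeks was 1 and 1 without ESS library 2, 6 and 5 without ESS library 1, 8 and 7 without ESS library 3, 65 and 61 without control library 2 and 2 and 3 without control library 3. It was 8 and 7 with the lone ESS library 3. With 3 control libraries the controls could not be divided into separate sets of at least 2 for each comparison.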

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

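Among the tests in this part, the one of induction in every ESS gland was chosen only after the result was seen, while the one of salivary carry-over was fixed before it.

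Salivary gland transcripts appeared in ESS libraries 1 and 2 in genes too low elsewhere to be tested. In ESS library 1 the values were 1061 FPKM for Dcpp1, 923 FPKM for Cst10, 576 FPKM for Dcpp3, 314 FPKM for Dcpp2, 179 FPKM for Klk1 and 69.7 FPKM for Prpmp5. ESS library 2 held 504, 538, 242, 147, 80.8 and 28.8 FPKM of the same genes, and none of the other 10 libraries held more than 0.670 FPKM.

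In ESS library 3 the median log2 ratio to control over the 10 listed genes was 0.29, against 9.18 and 8.27 in libraries 1 and 2. That restates the pattern and rests on 1 library, so it decides nothing about an induction in every ESS gland. Carry-over of salivary gland tissue predicts that salivary genes outside the list are raised too. Of 10 such genes, 2 (20%) were at least 4 times higher in both libraries than in any other, against 14 of 11716 other genes (0.119%), with Fisher's exact p = 7.81e-05. These 14 include salivary genes of the list, such as Bpifa2 and Amy1, which were left in the background. Carry-over is therefore a candidate explanation. The 11 genes with at least 20 FPKM that were raised in this way had ratios of library 1 to library 2 between 1.39 and 2.42 (median 1.82), as a share of tissue that differs between the samples may give. A response of ESS glands stays open, and one in some ESS glands alone was not tested.

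The effects against control of the NOD ages differed, by the comparison of 12 with 8 weeks itself, in 13 genes, of which 10 fall under the rule for named genes. From 8 to 12 weeks the effect against control moved by -2.18 for Scgb1b10, -1.29 for Igfbp3, -1.18 for Hspa8, -0.88 for Tsc22d3 and -0.82 for Coa6 on the log2 scale. It moved by 1.19 for Pigr, 1.15 for Asgr1, 0.97 for Calml4, 0.92 for Ifi27 and 0.69 for Slc25a35. The other 3, Npas2 (1.11), Myoc (0.99) and Olfm4 (0.84), were chosen after their values were seen.

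The effects against control also differed between ESS and NOD glands, by a test of the difference itself, in named genes that passed against control in both. Against 8 weeks the effect in ESS was lower for Jchain (-1.09) and Mt1 (-1.37) and higher for Scgb1b27 (1.87) and Ucn2 (0.44). Scgb1b27 had 120 and 50.5 FPKM in ESS libraries 1 and 2, which hold the salivary transcripts, and 22.2 FPKM in ESS library 3, against 16.2, 8.96 and 16.3 FPKM at 8 weeks. Against 12 weeks it was lower for Jchain (-1.96), Asgr1 (-1.17), Sardh (-0.70) and Mt1 (-1.41) and higher for Cbs (0.82). Of genes that passed in ESS but not in NOD glands against control, Cbs differed from 8 weeks (1.05), and Scgb1b27 (3.08), Cdc42se1 (-1.21) and Ctdsp2 (-1.47) differed from 12 weeks.

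Each comparison of 3 with 3 libraries allows 10 splits, so the smallest share they can give is 0.1 and none can be under 0.05. The real split gave 17 genes in ESS against control, where the highest of the others gave 5. It gave 2825 and 3444 in NOD against control at 8 and 12 weeks, where the highest others gave 1 and 3. It gave 13 between the NOD ages, where the highest other gave 1, and 1570 and 2128 in ESS against NOD at 8 and 12 weeks, where the highest others gave 3 and 1. Each other split mixes both groups on either side, so a real difference between them would itself widen the spread and lower the calls. The low counts of the other splits therefore do not measure what chance gives.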

How the results depend on the processing

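Rescaling without abundant genes and leaving out both ESS libraries with salivary transcripts were chosen after seeing the data, and the other alternatives before. Leaving out both leaves 1 ESS library, which is assumed to vary like the other groups. Of 10233 values of the 569 named results under other settings, 9277 kept their direction and side of the threshold, 145 newly passed, 655 no longer passed and 156 turned direction. Those 156 belong to 75 results, 80 of them come from leaving out 1 library, and 1 belongs to a called result, Il17re in ESS against NOD at 8 weeks, which became -0.01 with transcript values summed. Of 261 called results, 118 kept their call under every setting. The largest turned value was 0.857 in size, and the largest reported value that turned was Mup5 in ESS against control (1.60). A stricter filter leaves fewer genes to count, and the cause of the other changes was not tested. The replicate numbers did not pair the samples, since 18 pairs of libraries with the same number had correlations of -0.10 to 0.20 (median 0.011), with 1 over 0.1, and in 14 of 36 comparisons of a library with another group the best correlation was with its own number. As a replicate block they ended the call of interferon gamma response in NOD at 12 weeks against control (camera adjusted p = 0.0561), and gave calls of macrophage and monocyte markers in NOD at 8 weeks against control (camera adjusted p = 0.0330) and of cholesterol genes in ESS against NOD at 12 weeks (camera adjusted p = 0.0324). Absolute depth is unknown, so low values carry an unknown counting error. Values in parentheses below are log2 fold changes.

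With a pseudocount of 0.1, the count of changed genes was 11 in ESS against control. Shared calls were 8 between ESS and NOD at 12 weeks. Adipoq turned in NOD at 12 weeks against control, at 0.12.

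With no filter, the count of changed genes was 35 in ESS against control. Shared calls were 29 between ESS and NOD at 8 weeks and 29 between ESS and NOD at 12 weeks.

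With at least 5 FPKM in 3 libraries, the count of changed genes was 9 in ESS against control, 1681 in NOD at 8 weeks against control, 2168 in NOD at 12 weeks against control, 8 in 12 against 8 weeks in NOD and 1025 in ESS against NOD at 8 weeks. Lists called were 3 in ESS against control and 5 in NOD at 12 weeks against control. Shared calls were 7 between ESS and NOD at 8 weeks and 5 between ESS and NOD at 12 weeks.

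With quantile normalization, the count of changed genes was 27 in ESS against control and 24 in 12 against 8 weeks in NOD. Shared calls were 25 between ESS and NOD at 8 weeks and 23 between ESS and NOD at 12 weeks. Mup4 turned in NOD at 8 weeks against control, at -0.12, as did Egfl7 (0.060), Icam1 (0.021), Cdh5 (0.066) and Sdc1 (0.12). Chrm3 turned in NOD at 12 weeks against control, at 0.015, as did Ssb (0.082), Maf (0.00067), C1s1 (0.048), Clec10a (0.047) and Gzma (0.0031). Kit turned in ESS against NOD at 8 weeks, at -0.023, as did Mbp (-0.073). Cxcl13 turned in ESS against NOD at 12 weeks, at -0.091.

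With library medians centred, directions turned in ESS against control for Ltbr (0.032), Derl3 (0.029), Fabp4 (0.0027) and Sval2 (0.070). Sval2 turned in NOD at 8 weeks against control, at 0.053, as did Egfl7 (0.067), Icam1 (0.021), Cdh5 (0.070), Sdc1 (0.12) and Amy1 (0.019). Mup4 turned in NOD at 12 weeks against control, at 0.015, as did Chrm3 (0.020), Ssb (0.075), Maf (0.0064), C1s1 (0.027), Clec10a (0.061), Sval2 (0.12) and Gzma (0.022). Kit turned in ESS against NOD at 8 weeks, at -0.025, as did Mbp (-0.077). Cxcl13 turned in ESS against NOD at 12 weeks, at -0.075.

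With the 2 groups alone, the count of changed genes was 3 in ESS against control and 32 in 12 against 8 weeks in NOD. Lists called were 10 in 12 against 8 weeks in NOD. Shared calls were 2 between ESS and NOD at 8 weeks and 1 between ESS and NOD at 12 weeks.

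With the replicate number as a replicate block, the count of changed genes was 27 in ESS against control. Shared calls were 25 between ESS and NOD at 8 weeks and 25 between ESS and NOD at 12 weeks.

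With a fold change of at least 2 required, the count of changed genes was 8 in ESS against control, 510 in NOD at 8 weeks against control, 490 in NOD at 12 weeks against control, 6 in 12 against 8 weeks in NOD, 352 in ESS against NOD at 8 weeks and 326 in ESS against NOD at 12 weeks. Shared calls were 6 between ESS and NOD at 8 weeks and 4 between ESS and NOD at 12 weeks.

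With transcript values summed per gene, the count of changed genes was 2 in ESS against control and 5 in 12 against 8 weeks in NOD. Shared calls were 2 between ESS and NOD at 8 weeks and 2 between ESS and NOD at 12 weeks. Cxcl12 turned in ESS against control, at -0.85, as did Kit (0.38), Itgb2 (-0.24), Derl3 (0.069) and Mbp (-0.032). Fn1 turned in NOD at 8 weeks against control, at -0.28, as did Kit (0.046), Cxcl12 (-0.86), Egfl7 (0.14), Maf (-0.0032) and Mbp (-0.039). Cxcl12 turned in NOD at 12 weeks against control, at -0.49, as did Chrm3 (0.28) and Clec10a (0.14). Cxcl16 turned in 12 against 8 weeks in NOD, at -0.15, as did Birc5 (0.16). Il17re turned in ESS against NOD at 8 weeks, at -0.010.

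With rescaling without abundant genes, the count of changed genes was 63 in ESS against control and 26 in 12 against 8 weeks in NOD. Lists called were 8 in ESS against NOD at 12 weeks. Shared calls were 51 between ESS and NOD at 8 weeks and 53 between ESS and NOD at 12 weeks. Mbp turned in ESS against control, at -0.00021, as did Bcl6 (-0.034). Sval2 turned in NOD at 8 weeks against control, at 0.030, as did Egfl7 (0.0055) and Sdc1 (0.077). Mup4 turned in NOD at 12 weeks against control, at 0.056, as did Chrm3 (0.023), Ssb (0.11), C1s1 (0.042) and Sval2 (0.16). Kit turned in ESS against NOD at 8 weeks, at -0.082, as did Mbp (-0.13). C1s1 turned in ESS against NOD at 12 weeks, at -0.012, as did Cxcl13 (-0.11).

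With both ESS libraries with salivary transcripts left out, the count of changed genes was 552 in ESS against NOD at 8 weeks and 586 in ESS against NOD at 12 weeks. Shared calls were 8 between ESS and NOD at 8 weeks and 7 between ESS and NOD at 12 weeks. Mup5 turned in ESS against control, at -0.71, as did Fdps (-0.063), Sox10 (-0.0063), Egf (-0.083) and Sval2 (0.11). Cxcl13 turned in ESS against NOD at 12 weeks, at -0.41, as did Mbp (0.031).

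With an estimated correlation, the count of lists called was 0 in ESS against control, 0 in NOD at 8 weeks against control, 0 in NOD at 12 weeks against control, 0 in 12 against 8 weeks in NOD, 0 in ESS against NOD at 8 weeks and 0 in ESS against NOD at 12 weeks.

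With fry in place of camera, the count of lists called was 1 in ESS against control, 15 in NOD at 8 weeks against control and 0 in 12 against 8 weeks in NOD.

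With a pseudocount of 5, directions turned in NOD at 8 weeks against control for Bpifa2 (-0.039). Cma1 turned in NOD at 12 weeks against control, at -0.00034.

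With 1 library left out at a time, the count of changed genes ranged over 1 to 75 in ESS against control, 6 to 16 in 12 against 8 weeks in NOD and 1261 to 1906 in ESS against NOD at 12 weeks. The count of lists called ranged over 5 to 10 in ESS against control, 4 to 12 in 12 against 8 weeks in NOD and 5 to 8 in ESS against NOD at 12 weeks. The count of shared calls ranged over 1 to 65 between ESS and NOD at 8 weeks and 1 to 61 between ESS and NOD at 12 weeks. Directions then turned in ESS against control for Nkg7 (-0.52 to 0.012), Cpa3 (-0.079 to 0.63), Mcpt4 (-0.011 to 0.85), Tpsb2 (-0.12 to 0.82), Trp63 (-0.29 to 0.0030), Sox10 (-0.035 to 0.23), Esp1 (-0.25 to 0.041), Icam1 (-0.26 to 0.011), Lipe (-0.19 to 0.0011) and Serping1 (-0.16 to 0.33). So did Ltbr (-0.081 to 0.0063), Itgb2 (-0.13 to 0.34), Cfd (-1.02 to 0.45), Egf (-0.081 to 0.18), Car3 (-0.59 to 0.38), Derl3 (-0.11 to 0.086), Mbp (-0.0051 to 0.089), Fabp4 (-0.22 to 0.20), Bcl6 (-0.31 to 0.42) and Sval2 (-0.11 to 0.11). Directions then turned in NOD at 8 weeks against control for Tpsb2 (-0.055 to 0.89), Cpa3 (-0.15 to 0.56), Serping1 (-0.064 to 0.45), Cma1 (-0.77 to 0.092), Sdc1 (-0.13 to 0.061), Soat1 (-0.028 to 0.12), Smr3a (-0.29 to 1.77), Mbp (-0.077 to 0.17), Amy1 (-0.34 to 0.20) and Bpifa2 (-0.57 to 1.15). Directions then turned in NOD at 12 weeks against control for Maf (-0.36 to 0.083), Clec10a (-0.26 to 0.096), Sval2 (-0.18 to 0.022), Cfd (-1.14 to 0.17), Gzma (-0.59 to 0.20), Fabp4 (-0.057 to 0.40), Adipoq (-0.61 to 0.35), Cpa3 (-0.33 to 0.38) and Cma1 (-0.44 to 0.42). Directions then turned in 12 against 8 weeks in NOD for Il1b (-0.012 to 0.62), Ccl5 (-0.031 to 0.46), Egr1 (-1.34 to 0.16), Soat1 (-0.0059 to 0.14), Itgb2 (-0.015 to 0.35), Ikzf2 (-0.00020 to 0.14), Cdc20 (-0.11 to 0.34), Birc5 (-0.18 to 0.063), Sox10 (-0.017 to 0.13) and Mbp (-0.12 to 0.13). So did Thy1 (-0.18 to 0.16). Directions then turned in ESS against NOD at 8 weeks for Mbp (-0.13 to 0.12). Directions then turned in ESS against NOD at 12 weeks for Cxcl13 (-0.13 to 0.27) and Mbp (-0.048 to 0.0087).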

Other observations

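The tests of the histocompatibility region, of presentation genes on other chromosomes, of single genes with a copy and of clock genes were chosen only after the results were seen, while the test of the share with near-identical copies was fixed before it.

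Single genes of lists that did not pass fell in NOD glands. Of 3 tested genes of cytotoxic and NK cells, 2 fell at both ages, and the list did not pass (camera adjusted p = 0.155 and 0.479). Nkg7, a granule protein of these cells, had 0.207 ± 0.359 and 0.611 ± 0.218 FPKM at 8 and 12 weeks against 2.57 ± 0.566 FPKM in control, and the chemokine Ccl5 had 1.64 ± 0.698 and 2.22 ± 1.21 against 6.22 ± 1.66 FPKM. Among genes of duct epithelium, 4 and 5 of 9 fell at the 2 ages, and the tight junction gene Cldn3 went from 136 ± 9.81 to 96.9 ± 10.6 and 88.2 ± 12.5 FPKM (adjusted p = 0.00735 and 0.00153). The call of Cldn3 at 8 weeks ended with centred library medians, and its calls at both ages ended with a fold change of at least 2. That list did not pass either (camera adjusted p = 0.155 and 0.18).

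Of the genes whose proteins are autoantigens in Sjögren's syndrome, 7 were tested. Trim21, which encodes Ro52, fell in NOD glands from 2.40 ± 0.671 to 0.882 ± 0.207 and 1.02 ± 0.238 FPKM (adjusted p = 0.0046 and 0.00793) and had 1.67 ± 0.528 FPKM in ESS glands (adjusted p = 0.456). Ssb, which encodes La, had 36.2 ± 1.19 FPKM at 12 weeks and 39.3 ± 4.20 FPKM in control (adjusted p = 0.462). Sval2, a male-biased secreted gene, had 3271 ± 425 FPKM in ESS, 3004 ± 206 and 3099 ± 198 FPKM in NOD and 3277 ± 464 FPKM in control glands. The autoantigen list did not pass in ESS or NOD against control (camera adjusted p = 0.119, 0.467 and 0.846).

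A set of 37 genes fell at least 4-fold at both NOD ages, and histocompatibility genes stand out among them. A NOD haplotype of the histocompatibility region against the reference genome predicts that the region from 33996017 to 37274484 on chromosome 17 holds more than its share of them. It held 6 of the 37 (16.2%) against 0.807% of other tested genes (Fisher's exact p = 6.49e-07). That test restates the observation behind it, as the region begins at H2-K1, itself one of the falls, so it decides nothing and the haplotype stays open for the genes of the region. A mismatch of the haplotype to the reference genome cannot reach antigen presentation genes on other chromosomes, B2m, Cd74, Psmb10 and Erap1. Their median lay -1.05 and -0.496 relative to all genes at 8 and 12 weeks, so the mismatch leaves these falls unexplained. An effect of the haplotype on the expression of genes elsewhere was not tested. Of the other 31 genes, 29 had no near-identical copy of their longest transcript in another annotated gene, which argues against reads shared with such copies. Copies of shorter transcripts or outside the annotation could be missed, so reads shared with those stay open. Shared reads also stay open for the 2 with a copy, Rpl29 and Raet1e (6.45%, against 26 of 310 genes of the same level, 8.39%, Fisher's exact p = 1). Rps18, at 33951999 to 33956001 on chromosome 17, ends shortly before the region and was counted as outside it. For Rps18 the haplotype therefore stays open too. A difference of strain or age stays open.

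Genes of the morning and evening sides of the clock moved in opposite directions in 2 comparisons, which gave the hypothesis that glands were collected at another time of day. In ESS against control 13 of 15 clock genes went to one side of the cycle with 0 called, and their signed mean was 0.69 against -0.11 to 0.15 in random genes of the same level (permutation p = 0.0001, the smallest they can give). From 8 to 12 weeks in NOD glands 15 of 15 did so with 1 called, with a signed mean of 0.58 against -0.10 to 0.12 (permutation p = 0.0001, again the smallest). The 6 genes not among those first noticed gave 0.73 and 0.47 (permutation p = 0.0001 for each), a test added after the full result was seen. Clock genes vary together within a library and random genes do not, so these p-values overstate the evidence, and by library the real split gave differences of 0.69 and 0.58 where the highest other split gave 0.51 and 0.29, with 10 splits that cannot give a share under 0.05. Time of collection and a change of the clock in the animals cannot be told apart with 3 libraries per group.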
